A study of Mus musculus with 9 samples.

How the data were processed

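RNA was sequenced from the whole uterus of 9 female mice, 3 in each of 3 groups, killed at 13 weeks of age. Per the labels, tamoxifen mice received the drug, a selective estrogen receptor modulator, at 1 mg/kg as newborns, on days 1 to 5 of life. Tamoxifen+primidone mice received the same and, from week 10, primidone at 2 mg/kg per day for 3 weeks. Primidone is an anticonvulsant that is also known to block the ion channel TRPM3. Control mice received neither drug, but a treatment that the labels call vesicle, read here as vehicle. Each library was assigned to its group and replicate number from its label, and all 9 were used.

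Per the submitters' processing notes, HISAT2, HTSeq, R 3.2.0 and DESeq2 were used and the genome build was GRCm39. The annotation, the versions of the other tools and the strand setting of the counting are not given in the sources used here. The authors deposited whole-number read counts per gene symbol for 18094 genes, not normalized. The authors also deposited FPKM values for the same genes, which are scaled for library size and gene length. Gene lengths recovered from the ratio of counts to FPKM were whole numbers within 0.01 for 99.97% of the genes. The reference used here is of another build than the authors', so it served only for gene symbols and GC content, which was found for 97.69% of the tested genes, and no coordinates are given. The table holds 0 mitochondrially encoded genes, so their share could not serve as a sign of RNA quality.

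Library totals ran from 36393120 to 39958443 counts. Replicates of a group differed far beyond counting noise, with a chi-square per degree of freedom from 20.24 to 81.35 over the 9 pairs, so no library was counted as a repeat of another. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. Values of closely related genes with few counts (the Klra, Mup, Sprr2, Hba and Hbb families) are uncertain, because reads may be split among the copies.

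Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, using TMM normalization, the default low-count filter by group and robust dispersion estimation. All 9 libraries entered a single fit with a coefficient per group, and 15186 genes passed the filter. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.2026, and estimated within groups it was 15.38% in control, 20.99% in tamoxifen and 23.57% in tamoxifen+primidone libraries. Contrasts were tamoxifen against control, tamoxifen+primidone against tamoxifen and tamoxifen+primidone against control, with an F test of any difference among the 3 groups. Levels are CPM, counts divided by TMM-scaled library sizes, given as mean ± SD over 3 libraries. Log2 fold changes are given ± an approximate standard error. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and is rough for genes with few counts.

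Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 34 lists with at least 3 tested members. Lists covered TRP channels, smooth muscle, fibrosis and extracellular matrix, epithelial-mesenchymal transition, endometrial glands, uterine epithelium, endometrial stroma, estrogen-responsive and progesterone-responsive uterine genes, steroid hormone receptors and metabolism, and cell cycle. They also covered inflammatory cytokines, interferon response, prostaglandin pathway, uterotonic receptors, calcium and potassium channels, hypoxia and glycolysis, Muellerian patterning, immediate early and heat shock genes, and liver genes known to be induced by barbiturates. Cell type lists were nerve and Schwann cells, endothelium, neutrophils, macrophages, T and NK cells, B and plasma cells, mast cells, eosinophils, adipocytes, ovary and oviduct, stratified squamous epithelium, skeletal muscle, erythroid cells and mesothelium. Y-linked and mitochondrially encoded genes had 0 tested members. The groups, tests, lists, the first set of alternatives and the rule for named genes were fixed before the data were examined.

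Genes named in the text are, for each comparison and direction, the 10 with the largest log2 fold change among those that passed, with at least 2 CPM in the higher group, non-overlapping ranges of the 3 libraries of each group and a named gene. Where fewer than 5 passed, the genes with the smallest p made up 5. For each list that passed, up to 4 members with the smallest p were added, and for TRP channels every member that passed, the 5 with the highest mean CPM and Trpm3. Other members of the lists are named as examples where they passed, and were chosen after their values were seen.

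The edgeR procedure was tested on simulated data, with counts drawn from the means and library sizes of the real genes. For tamoxifen against control (15020 genes), 64 of 98 genes simulated with a 2-fold change (65.3%) and 85 of 100 with a 4-fold change (85%) were recovered, with 7 false calls. For tamoxifen+primidone against tamoxifen (15044 genes), 56 of 96 (58.3%) and 79 of 100 (79%) were recovered, with 14 false calls. For tamoxifen+primidone against control (15042 genes), 63 of 100 (63%) and 88 of 99 (88.9%) were recovered, with 7 false calls.

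Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with and without a filter, other size factors, other filters, a fit of only the groups compared, replicate number as a block, a surrogate variable from sva 3.50.0, removal of gene-length or GC trends, other thresholds, and leaving out each library in turn. For gene lists they were camera with an estimated correlation, fry and another prior count. Added after the data were seen were a batch term based on liver transcripts, counts without liver genes, library weights in limma, and marker lists of liver, clock, NK cell, Klra receptor, brain, kidney, pancreas, heart and intestine genes. Overlaps of comparisons that share libraries were set against 50 simulations of unchanged groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.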

Results

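Gene expression was measured by RNA sequencing in the uterus of 9 adult female mice, 3 each in a control group, a group given tamoxifen as newborns, and a group given tamoxifen as newborns followed by primidone as adults. Neonatal tamoxifen is used to model adenomyosis, in which endometrium grows into the muscle of the uterus. Total counts were 39169029, 37474063 and 38197855 in the control libraries, 39958443, 36393120 and 39837883 in the tamoxifen libraries and 36847379, 38063309 and 39052190 in the tamoxifen+primidone libraries. The gene with the most counts was Clca1 in each control library and in tamoxifen+primidone replicates 2 and 3. It was C3 in each tamoxifen library and Eef1a1 in tamoxifen+primidone replicate 1. On the first principal component, with 27.23% of the variance, control libraries lay at −38.68, −37.59 and −43.9, tamoxifen libraries at 13.26, 21.86 and 18.25, and tamoxifen+primidone libraries at 22.42, 29.56 and 14.81.

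**Figure D1:**
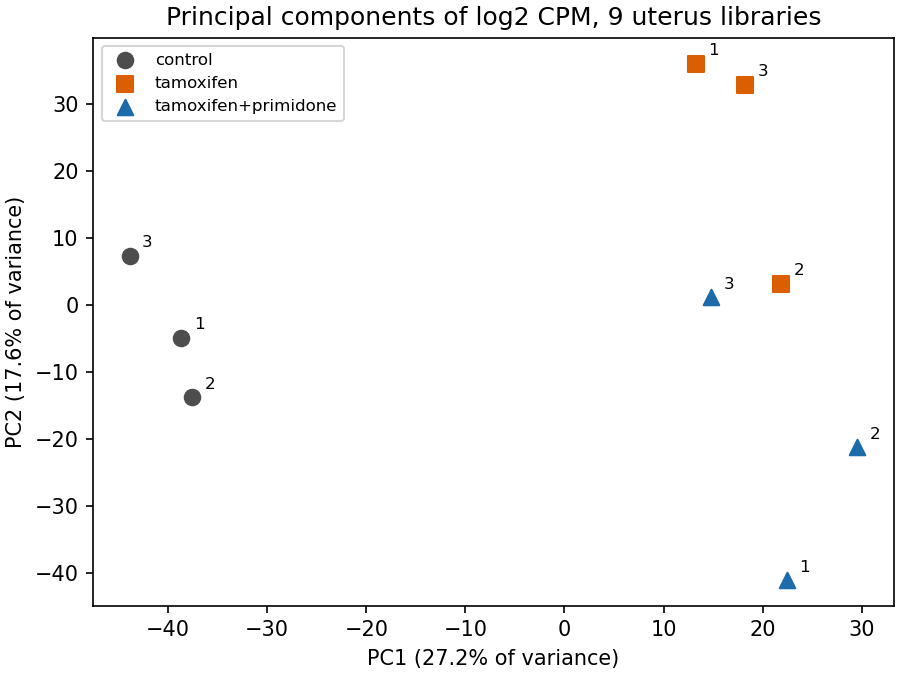
Principal components of log2 CPM in the 9 libraries, with the share of variance on each axis and replicate numbers beside the points. The 3 control libraries lie between −43.9 and −37.59 on the first component and the other 6 libraries between 13.26 and 29.56.

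The first comparison addressed how the adult uterus of mice given tamoxifen as newborns differed from that of control mice. Slc5a8, a sodium-coupled transporter of short-chain fatty acids, rose 24.4-fold, from 1.03 ± 0.129 to 25.2 ± 7.3 CPM (SD, n = 3; log2 fold change 4.61 ± 0.66, edgeR adjusted p = 0.024). Arntl, a core activator of the circadian clock, rose 4.14-fold, from 9.18 ± 1.21 to 38 ± 4.08 CPM (adjusted p = 0.00025), and Dbp, a clock-controlled transcription factor, fell from 129 ± 25.5 to 17.4 ± 3.63 CPM (log2 fold change −2.89 ± 0.33, adjusted p = 0.0096). Cenpf, which encodes a kinetochore protein, fell by 2.47 ± 0.47 on the log2 scale and Cdca3, a regulator of mitotic entry, by 2.36 ± 0.39. Eln, which encodes elastin, rose from 78.7 ± 14.2 to 228 ± 41.4 CPM (log2 fold change 1.53 ± 0.22, adjusted p = 0.023).

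Of 15186 genes tested, 87 were higher and 146 lower in tamoxifen than in control libraries, 45 and 75 of them by over 2-fold. DESeq2 called 523 and 589, limma-voom 50 and 118, and 2699 genes had an unadjusted p under 0.05 where chance gives 759. Ranges of the 3 libraries did not overlap for 3967 genes (26.1%, against 10% by chance). Such chance values are averages, and since genes vary together, a single split of the libraries can lie far from them. Further genes with large increases were Klra8, a receptor of natural killer cells (5.19 ± 0.95), Nox1, an NADPH oxidase (4.76 ± 0.92), Krt6b, a keratin (3.55 ± 0.6), F10, coagulation factor X (2.38 ± 0.5), Crabp1, a retinoic acid binding protein (2.18 ± 0.42), and Msln, mesothelin (1.9 ± 0.35), with Asprv1 at 1.88 ± 0.34 and Smtnl2 at 1.81 ± 0.35. Among the genes with large decreases were Abcb5, an ABC transporter (−6.35 ± 0.87), Atp4a, a proton pump subunit (−3.17 ± 0.61), Tinag (−3.12 ± 0.5), Gja3, a connexin (−2.91 ± 0.56), Ciart, a repressor of the clock (−2.91 ± 0.47), Psmc3ip, a factor of homologous recombination (−2.63 ± 0.27), and Neil3, a DNA glycosylase (−2.37 ± 0.4). Leaving out 1 library changed the total of 233 genes to 22 without control 1, 75 without control 2, 36 without control 3, 42 without tamoxifen 1, 103 without tamoxifen 2, 61 without tamoxifen 3 and 439 without tamoxifen+primidone 1. Of the 31 named genes that passed, Arntl, Psmc3ip and P4ha1 passed with each of the 9 libraries left out. In all, 27 were lost without control 1, 25 without control 2, 26 without control 3, 28 without tamoxifen 1, 19 without tamoxifen 2, 24 without tamoxifen 3, 1 without tamoxifen+primidone 1 and 3 without tamoxifen+primidone 3, with edgeR adjusted p up to 0.16.

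By gene list, 11 of 34 lists passed camera in tamoxifen against control, 8 up and 3 down, and 0 passed with an estimated correlation or with fry. In the cell cycle list, 29 of 30 members had negative log2 fold changes (median −1.52, adjusted p = 8.47e-11, or adjusted p = 0.603 with an estimated correlation). Of these members 6 fell, including Kif20a (−2.06 ± 0.34), Cdc20 (−2.11 ± 0.37), Bub1b (−1.87 ± 0.34) and Ube2c (−2.13 ± 0.39), which act in mitosis, and 18 fell when adjusted over the list alone. All 15 tested hypoxia and glycolysis genes had positive log2 fold changes (median 0.7, adjusted p = 4.84e-08, or adjusted p = 0.603 with an estimated correlation). Of these, 3 rose, namely Hk2, a hexokinase (1.56 ± 0.23), P4ha1, a collagen prolyl hydroxylase (1.02 ± 0.13), and Slc2a1, a glucose transporter (0.92 ± 0.19), and 10 rose when adjusted over the list alone. Smooth muscle genes were lower as a list (median −0.42, 19 of 20 negative, adjusted p = 5.73e-06, or adjusted p = 0.603 with an estimated correlation). None of its members passed over all genes, with Myl9 at −0.65 ± 0.15 (adjusted p = 0.066) and Myh11 at −0.59 ± 0.16 (adjusted p = 0.093), and 10 passed when adjusted over the list alone. The mean log2 level of this list relative to the 9 libraries was 0.428 and 0.479 in controls 1 and 3 but −0.097 in control 2, within the range of the tamoxifen libraries (−0.224 to −0.043).

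Of the immune lists, T and NK cell markers were higher (median 0.94, 12 of 15 positive, adjusted p = 3.39e-05, or adjusted p = 0.603 with an estimated correlation), and Il2rb, an interleukin receptor chain, rose by 0.94 ± 0.17. Neutrophil markers were higher as a list (median 1.12, 8 of 8 positive, adjusted p = 0.00768, or adjusted p = 0.603 with an estimated correlation), while S100a9, with 4.93 ± 3.48 CPM in tamoxifen and 0.375 ± 0.276 in control libraries, did not pass alone (adjusted p = 0.13). Inflammatory cytokines were higher as a list (median 0.31, 20 of 27 positive, adjusted p = 0.0367, or adjusted p = 0.708 with an estimated correlation), a call lost without control 3 or tamoxifen 2, at up to 0.27. Within that list, Nos2, an inducible nitric oxide synthase that did not pass alone (adjusted p = 0.082), stood at 12.2 CPM in tamoxifen replicate 2 and at 1.28 and 1.92 in the other tamoxifen libraries. Mast cell markers were lower (median −1.36, 4 of 6 negative, adjusted p = 0.0326, or adjusted p = 0.603 with an estimated correlation), with the proteases Mcpt4 and Tpsb2 each at −2.04 and past the test. That call was lost without control 3, tamoxifen+primidone 1 or tamoxifen+primidone 2, at up to 0.073. Fibrosis and extracellular matrix genes had a median of 0.17 (24 of 33 positive, adjusted p = 0.0385, or adjusted p = 0.782 with an estimated correlation), and Eln alone passed over all genes. The list was lost without control 2, control 3, tamoxifen 1 or tamoxifen 3, at up to 0.41.

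Markers of other tissue moved with the tamoxifen group as well. Adipocyte markers were higher as a list (median 1.28, adjusted p = 0.00852, or adjusted p = 0.708 with an estimated correlation; lost without tamoxifen 3, at 0.17), and Adipoq stood at 26.3 CPM in tamoxifen 3 against 7.24 and 3.2 in the other tamoxifen libraries. Mesothelium markers had a median of 0.64 (adjusted p = 0.00844, or adjusted p = 0.603 with an estimated correlation), with Msln past the test. Erythroid markers had a median of 1.21 (adjusted p = 0.0121, or adjusted p = 0.603 with an estimated correlation; lost without control 3, at 0.073), with 0 of 6 members past the test. In a liver marker list drawn up after the data were seen, 36 of 39 tested genes had positive log2 fold changes (median 0.94) and 5 rose. Tamoxifen 3 stood apart, with a median log2 level over the control mean of 1.64 against 0.59 and 0.29 in tamoxifen 1 and 2.

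**Figure D2:**
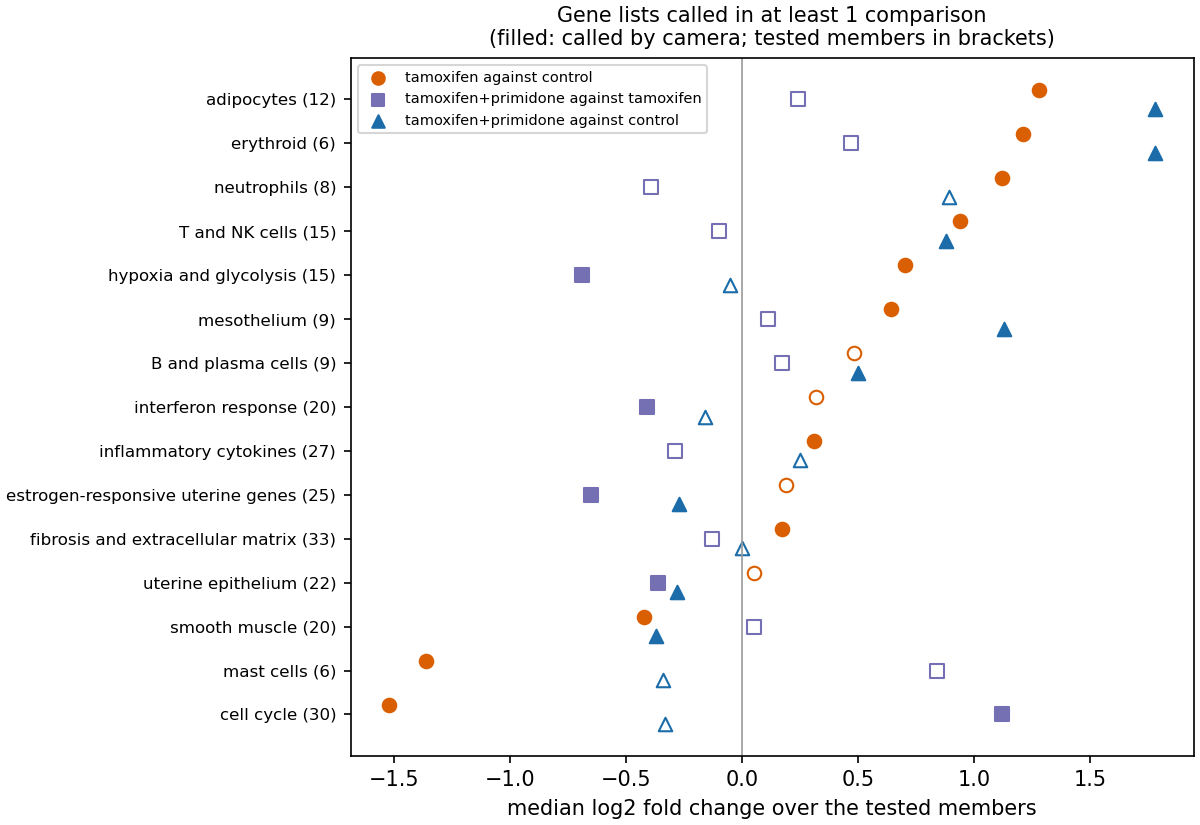
Median log2 fold change over the tested members of each gene list that passed camera in at least 1 comparison, with the number of tested members in brackets and filled symbols for lists that passed. Cell cycle genes lie at −1.52 in tamoxifen against control and at 1.12 in tamoxifen+primidone against tamoxifen.

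The second comparison addressed the effect of 3 weeks of primidone in mice given tamoxifen as newborns. Hgfac, a protease that activates hepatocyte growth factor, fell from 110 ± 20.5 to 36.8 ± 1.32 CPM (n = 3; log2 fold change −1.57 ± 0.15, edgeR adjusted p = 0.012). Tmprss11d, an airway-type transmembrane serine protease, fell from 37.5 ± 1.97 to 12.1 ± 3.54 CPM (−1.63 ± 0.19, adjusted p = 0.042). As lists, cell cycle genes were higher and hypoxia and glycolysis, estrogen-responsive, uterine epithelium and interferon response genes lower. Of these calls, that of the estrogen-responsive list held with an estimated correlation (adjusted p = 0.0228). The others had an adjusted p with an estimated correlation of 0.79 for cell cycle, 0.474 for hypoxia and glycolysis, 0.474 for uterine epithelium and 0.79 for interferon response genes.

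With edgeR, 0 genes were higher and 2 lower, while 2096 genes had an unadjusted p under 0.05 where chance gives 759. DESeq2 called 211 and 367 genes, limma-voom 0 and 3, and limma on log2(FPKM + 1) 0 and 2. With other settings edgeR called 13 and 57 with a surrogate variable, 3 and 18 without a low-count filter and 3 and 12 with the gene-length trend removed. Ranges of the 3 libraries did not overlap for 2525 genes (16.6%, against 10% by chance). Mixed splits of these 6 libraries called up to 40 genes with edgeR, more than the 2 of the real groups. An excess over the chance values is therefore no sign of a primidone effect by itself. Genes with the smallest p that did not pass were Psmc3ip (1.81 ± 0.27), Mgp, matrix Gla protein (0.91 ± 0.13), Ccnd2, cyclin D2 (0.63 ± 0.08), Ces2b (−1.06 ± 0.14), Rasd1 (−0.87 ± 0.12) and Papln (−1.2 ± 0.17), each at an adjusted p of 0.052, and Nkd1 (0.57 ± 0.1) and Hmgn2 (0.52 ± 0.09) at 0.072. Leaving out 1 library gave 0 genes without control 1, 1 without tamoxifen 1, 17 without tamoxifen 2, 11 without tamoxifen 3, 85 without tamoxifen+primidone 1, 5 without tamoxifen+primidone 2 and 15 without tamoxifen+primidone 3. Without control 2 there were 3 and without control 3 there were 2. Both Hgfac and Tmprss11d were lost without control 1 or tamoxifen 1, and Tmprss11d also without control 3, with edgeR adjusted p up to 0.15.

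Of 34 lists, 5 passed camera in tamoxifen+primidone against tamoxifen, and each kept its call with each of the 9 libraries left out. By the same test, 6 of the 10 splits of these 6 libraries, the real one among them, called at least 5 lists (highest other 14). The number of lists called thus does not set the real groups apart from mixed ones. All 30 cell cycle genes had positive log2 fold changes (median 1.12, adjusted p = 4.64e-12, or adjusted p = 0.79 with an estimated correlation). None passed over all genes and 25 passed when adjusted over the list alone, with Mcm3, a replication helicase subunit, at 1.02 ± 0.23 and Tyms, thymidylate synthase, at 0.66 ± 0.17. The mean log2 level of the list relative to the 9 libraries was 0.747 and 0.558 in tamoxifen+primidone replicates 2 and 3 and −0.762 in replicate 1, against −0.566, −0.803 and −0.724 in the tamoxifen libraries. All 15 hypoxia and glycolysis genes had negative log2 fold changes (median −0.69, adjusted p = 4.79e-10, or adjusted p = 0.474 with an estimated correlation). None passed over all genes and 12 passed when adjusted over the list alone, with Pdk1, a kinase that inhibits pyruvate dehydrogenase, at −1.07 ± 0.17 and Aldoa, aldolase A, at −0.39 ± 0.09.

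Estrogen-responsive uterine genes fell as a list with both settings of the correlation (median −0.65, 22 of 25 negative, adjusted p = 2.96e-09, and adjusted p = 0.0228 with an estimated correlation). Ltf, lactotransferrin, stood at 4050 ± 774 CPM against 9270 ± 1930 in tamoxifen libraries (−1.19 ± 0.18, adjusted p = 0.054), Sprr2f at 1370 ± 348 against 2760 ± 333 (−1 ± 0.17, adjusted p = 0.074) and complement C3 at 12500 ± 2220 against 21000 ± 2220 (−0.75 ± 0.17, adjusted p = 0.12). None of the members passed over all genes and 9 passed when adjusted over the list alone. Uterine epithelium genes had a median of −0.36 (19 of 22 negative, adjusted p = 5.43e-10, or adjusted p = 0.474 with an estimated correlation), with 15 lower and 1 higher when adjusted over the list alone. Examples were the tight junction genes Cldn4 (−0.46 ± 0.08) and Cldn3 (−0.43 ± 0.08), neither past the test over all genes. Interferon response genes had a median of −0.41 (20 of 20 negative, adjusted p = 9.23e-05, or adjusted p = 0.79 with an estimated correlation), and 0 passed alone, with Oasl1 at −0.92 ± 0.26. The groups overlapped in the level of this list, which was 0.573, 0.549 and −0.405 in the tamoxifen libraries and −0.5, 0.343 and −0.53 in the tamoxifen+primidone libraries. With fry, the estrogen-responsive (adjusted p = 0.0061) and uterine epithelium (adjusted p = 0.0476) lists passed. The stage of the estrous cycle, with which levels of estrogen-responsive, epithelial and cell cycle genes in the uterus are known to vary, is not given in the sources used here. In the liver marker list drawn up after the data were seen, 37 of 39 genes had positive log2 fold changes in this comparison (median 0.84), and 0 passed with edgeR. This difference rests on tamoxifen 1 and 2, with median log2 levels over the control mean of 0.59 and 0.29. Tamoxifen 3 stood at 1.64, beside 1.64, 1.9 and 1.82 in the tamoxifen+primidone libraries.

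**Figure D3:**
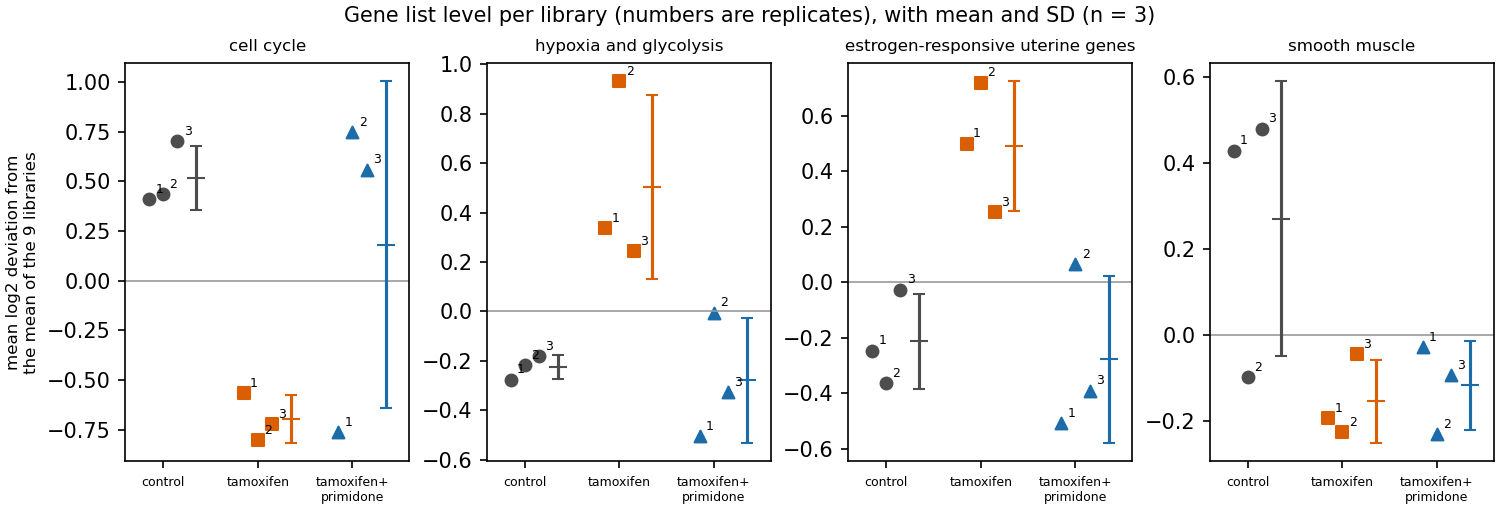
Mean log2 deviation of 4 gene lists from the mean of the 9 libraries, per library with the replicate number, and mean ± SD per group (n = 3). The cell cycle list lies at −0.762 in tamoxifen+primidone replicate 1 and at 0.747 and 0.558 in replicates 2 and 3.

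The third comparison measured how far the uterus of mice given tamoxifen and then primidone lay from that of control mice. Ltf fell from 8330 ± 196 to 4050 ± 774 CPM (n = 3; log2 fold change −1.04 ± 0.18, edgeR adjusted p = 0.014), and Elf3, an epithelial transcription factor, fell from 1080 ± 36.5 to 719 ± 23.9 CPM (−0.59 ± 0.09, adjusted p = 0.0092). Samd11 rose from 1.19 ± 0.127 to 7.61 ± 2.14 CPM (2.68 ± 0.33, adjusted p = 0.0043). Serpina1e, a protease inhibitor made mainly in the liver, rose from 2.78 ± 0.478 to 16.8 ± 1.3 CPM (2.6 ± 0.29, adjusted p = 0.0036). Il2rb rose from 10 ± 1.65 to 23.2 ± 2.08 CPM (1.21 ± 0.17, adjusted p = 0.0079).

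There were 325 genes higher and 487 lower, 111 and 93 of them by over 2-fold, with 3523 genes at an unadjusted p under 0.05. The split was 431 higher and 400 lower under upper-quartile factors, which change the scaling alone. With limma on FPKM, where test and scaling both differ, it was 659 and 337 on log2(FPKM + 1), 646 and 316 with log2(FPKM + 0.1), and 468 and 236 without a filter on FPKM. DESeq2 called 894 and 988. Ranges did not overlap for 4425 genes (29.1%, against 10% by chance). Large increases were found for the natural killer cell receptors Klra8 (5.92 ± 0.96), Klrc3 (4.32 ± 0.97) and Klri2 (2.48 ± 0.62), Lhx8, a homeobox factor (2.96 ± 0.69), Slc15a1, a peptide transporter (2.67 ± 0.65), Entpd3 (2.43 ± 0.47), and the liver-expressed genes Mup14 (2.87 ± 0.47) and Fga, a fibrinogen chain (2.62 ± 0.45). Large decreases were found for Glycam1 (−4.36 ± 1.01), Abcb5 (−4.2 ± 0.73), Ifi27l2b (−3.39 ± 0.83), Psg27 (−3.21 ± 0.46), Galnt13 (−3.16 ± 0.59), Srd5a2, a steroid reductase (−3.14 ± 0.46), Pcdh11x (−2.95 ± 0.5), Topaz1 (−2.88 ± 0.52), Ly6f (−2.86 ± 0.57) and Ciart (−2.69 ± 0.47). Leaving out 1 library changed the total of 812 genes to 122 without control 1, 363 without control 2, 178 without control 3 and 334 without tamoxifen+primidone 2. Of the 38 named genes that passed, Elf3, Il2rb, Psg27, Samd11, Serpina1e, Spint1 and Srd5a2 passed with each of the 9 libraries left out. In all, 31 were lost without control 1, 17 without control 2, 27 without control 3, 8, 3 and 6 without tamoxifen 1, 2 and 3, and 16, 16 and 11 without tamoxifen+primidone 1, 2 and 3, with edgeR adjusted p up to 0.16.

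By gene list, 8 of 34 passed camera in tamoxifen+primidone against control and 0 with an estimated correlation or with fry. Uterine epithelium genes were lower (median −0.28, 18 of 22 negative, adjusted p = 8.2e-05, or adjusted p = 0.797 with an estimated correlation), and 5 of them fell, among them Spint1, a protease inhibitor (−0.53 ± 0.08), Muc1, a mucin (−0.68 ± 0.14), and Esrp1, a splicing regulator (−0.34 ± 0.07). When adjusted over the list alone, 10 fell. Smooth muscle genes were lower (median −0.37, 19 of 20 negative, adjusted p = 0.000858, or adjusted p = 0.797 with an estimated correlation), and Actg2, smooth muscle actin (−1.18 ± 0.22), and Myh11, smooth muscle myosin (−0.69 ± 0.16), fell, with 11 members lower when adjusted over the list alone. Control 2 stood apart here too, with a list level of −0.097 beside −0.027, −0.23 and −0.092 in the tamoxifen+primidone libraries and with Actg2 at 562 CPM against 887 and 1070 in controls 1 and 3. Estrogen-responsive genes were called down (adjusted p = 0.031, or adjusted p = 0.797 with an estimated correlation; lost without control 3 or tamoxifen+primidone 1, at up to 0.1). Their median was −0.27 and their mean 0.06, with 14 of 25 negative. Of these, 5 fell, among them Ltf, Padi1, a peptidylarginine deiminase (−0.88 ± 0.19), and Greb1 (−1.07 ± 0.25), and 8 fell when adjusted over the list alone.

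T and NK cell markers were higher (median 0.88, 11 of 15 positive, adjusted p = 0.00573, or adjusted p = 0.797 with an estimated correlation), and Il2rb and Nkg7, a granule protein (1.6 ± 0.26), rose, with 8 higher when adjusted over the list alone. B and plasma cell markers had a median of 0.5 (9 of 9 positive, adjusted p = 0.0422, or adjusted p = 0.797 with an estimated correlation), and Mzb1 rose by 0.99 ± 0.2. That list was lost without control 1, control 3, tamoxifen+primidone 1 or tamoxifen+primidone 3, at up to 0.14. Markers of other tissue also moved with this group. Adipocyte markers had a median of 1.78 (adjusted p = 0.00607, or adjusted p = 0.797 with an estimated correlation; lost without tamoxifen+primidone 2, at 0.074), with Adipoq at 27.7 CPM in replicate 2 against 8.48 and 6.04 in the other tamoxifen+primidone libraries. Mesothelium markers had a median of 1.13 (adjusted p = 0.0153, or adjusted p = 0.797 with an estimated correlation), and Msln, Wt1 and Lrrn4 rose. Erythroid markers had a median of 1.78 (adjusted p = 0.0154, or adjusted p = 0.797 with an estimated correlation; lost without control 3 or tamoxifen+primidone 1, at up to 0.12), and Hbb-bs rose from 61.8 ± 16.4 to 224 ± 114 CPM. In the liver list drawn up after the data were seen, 38 of 39 genes had positive log2 fold changes (median 1.85) and 22 rose.

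TRP channels, a family of cation channels named in the title of the series, were described as a list of 28 genes, of which 26 were in the table, 20 were tested and 10 had a mean of at least 10 CPM. Trpv6, a calcium-selective channel of epithelia, was the member with the highest level, at 261 ± 51.5 CPM in control, 268 ± 57.4 in tamoxifen and 146 ± 26.2 in tamoxifen+primidone libraries (n = 3). It fell in tamoxifen+primidone against control (log2 fold change −0.84 ± 0.19, edgeR adjusted p = 0.041). Against tamoxifen its log2 fold change was −0.88 ± 0.19 (adjusted p = 0.12 over all genes and 0.024 when adjusted over the list alone), and tamoxifen against control gave 0.04 ± 0.19 (adjusted p = 0.94). The call against control was lost without control 1, 2 or 3, tamoxifen 1, or tamoxifen+primidone 1 or 3, at up to 0.12.

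No other tested TRP gene passed in any comparison, and adjusted over the list alone 0, 1 and 1 genes passed in the 3 comparisons, Trpv6 in both cases. Levels of Pkd2 were 87.6 ± 5.96, 81.1 ± 12.6 and 87.3 ± 2.4 CPM in control, tamoxifen and tamoxifen+primidone libraries. Those of Trpm4 were 85.7 ± 11.2, 74.6 ± 5.91 and 66.2 ± 11.7 CPM (−0.37 ± 0.14 in tamoxifen+primidone against control, adjusted p = 0.14). Trpm7 stood at 80.7 ± 4.6, 67 ± 3.75 and 70.9 ± 5.43 CPM (−0.27 ± 0.08 in tamoxifen against control, adjusted p = 0.14), and Trpv4 at 25.5 ± 1.21, 26.4 ± 2.83 and 29.7 ± 10.7 CPM. Trpm3, the channel that primidone is known to block, was near the limit of detection, at 0.729 ± 0.121, 0.407 ± 0.265 and 0.484 ± 0.282 CPM, and a difference was not detectable at this depth (−0.84 ± 0.67 in tamoxifen against control, adjusted p = 0.55). As a list, TRP channels did not pass camera, with adjusted p of 0.655, 0.614 and 0.403 in the 3 comparisons.

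**Figure D4:**
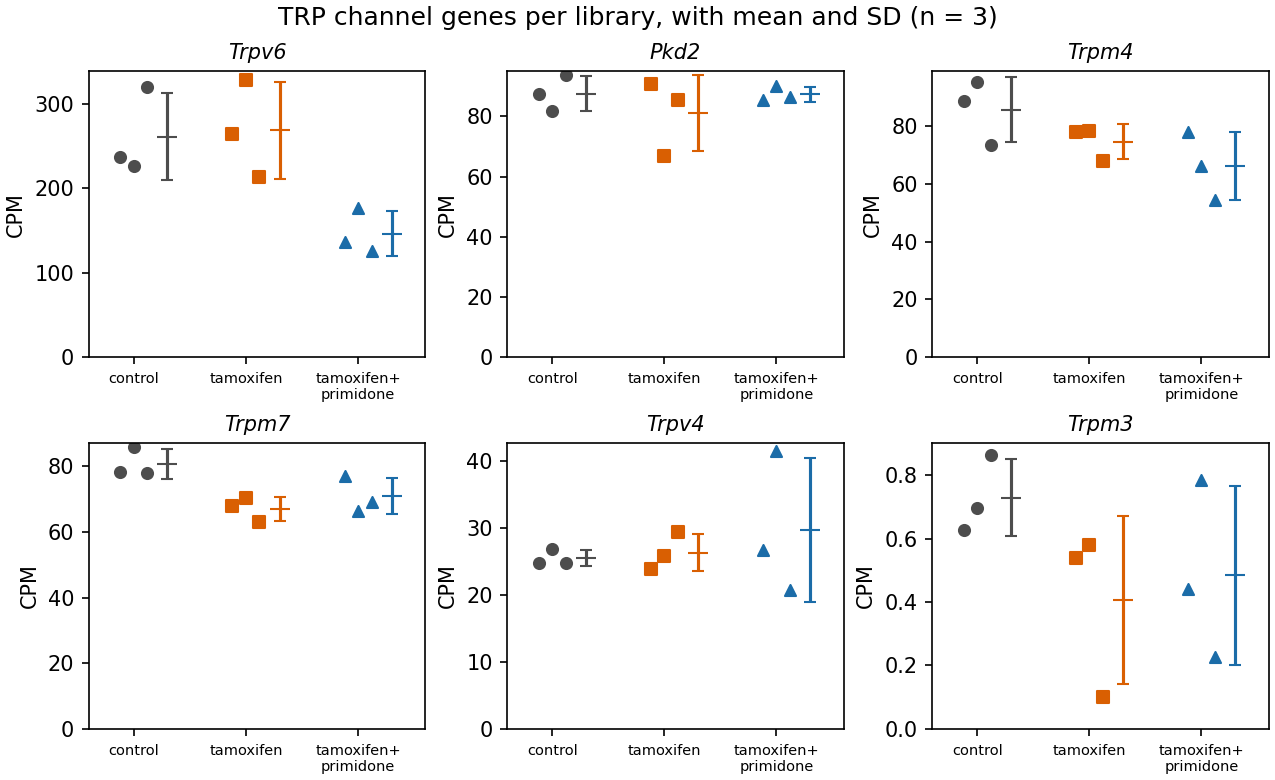
CPM of 6 TRP channel genes per library, with mean ± SD per group (n = 3). Trpv6 lies at 136, 176 and 126 CPM in the tamoxifen+primidone libraries and between 213 and 328 CPM in the other 6 libraries.

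Across the 3 groups together, 583 genes differed (edgeR F test; 3558 at an unadjusted p under 0.05). This number was 59 without control 1, 204 without control 2, 79 without control 3, 272 without tamoxifen 1 and 378 without tamoxifen 3. Tamoxifen against control and tamoxifen+primidone against control shared 136 called genes with the same sign and 0 with opposite signs. Independent lists of these sizes would share 1.86 higher and 4.68 lower genes. Simulated groups without effect that share the control libraries gave 0.04. With no effect few genes can pass in either comparison, so 0.04 does not measure what shared controls add among called genes. Across genes, which are not independent replicates, their log2 fold changes had r = 0.669, where simulation gave 0.499, and a covariance of 0.2285 against a simulated 0.0616, a difference of 0.1669. Part of the excess may come from the shared control libraries, which are too few to be split.

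A further question was which genes changed by tamoxifen moved back with primidone. Tmprss11d alone passed in both comparisons with opposite signs, 0.92 in tamoxifen against control (edgeR adjusted p = 0.043) and −1.63 in tamoxifen+primidone against tamoxifen. Its levels were 20.4, 16.7 and 22.4 CPM in control and 39.3, 37.7 and 35.4 in tamoxifen libraries. In tamoxifen+primidone libraries they were 9.98, 16.2 and 10.1, below each control library. The gene thus went below the control level and did not only return to it. Independent lists would give 0.0115 genes that pass in both comparisons with opposite signs. Simulation with the shared tamoxifen libraries gave 0.02, but it held no tamoxifen effect, so a count near 0 was set in advance. The number of such genes was 135 with DESeq2 and 1 with limma-voom. Leaving out 1 library gave 0 without control 1, 2 or 3 or tamoxifen 1 or 3, 4 without tamoxifen 2, and 49, 3 and 2 without tamoxifen+primidone 1, 2 and 3. Of the 233 genes called in tamoxifen against control, 161 (69.1%) had the opposite sign in tamoxifen+primidone against tamoxifen. Of the genes at an unadjusted p under 0.05 in the first comparison, 66.7% did, where simulation with the shared tamoxifen libraries and no effect gave 89.1%. Over all genes 58.5% did, where simulation gave 66.6%. Without a tamoxifen effect in the simulation, its shares are no baseline for genes that tamoxifen changed. The log2 fold changes had r = −0.416, where simulation gave −0.5, and a covariance of −0.1161 against −0.0616, a difference of −0.0545.

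The remaining lists did not pass in any comparison, and the smallest adjusted p by camera is given for each. For lists of the uterine wall it was 0.351 for epithelial-mesenchymal transition, 0.202 for endometrial glands, 0.403 for endometrial stroma, 0.0711 for Muellerian patterning and 0.604 for endothelium and angiogenesis. Hormone-related lists stood at 0.0961 for progesterone-responsive genes, 0.291 for steroid hormone receptors and metabolism and 0.614 for the prostaglandin pathway. For excitability the values were 0.613 for uterotonic receptors, 0.403 for calcium and potassium channels and 0.367 for nerve and Schwann cells. Other cells gave 0.0541 for macrophages, 0.419 for eosinophils, 0.403 for ovary and oviduct, 0.593 for stratified squamous epithelium and 0.0743 for skeletal muscle, and immediate early and heat shock genes 0.182. Barbiturate-inducible drug metabolism genes had an adjusted p of 0.742, 0.919 and 0.916 in the 3 comparisons, with medians of 0.06, 0.02 and 0.13 and means of 0.17, 0.09 and 0.26, although the direction of the test was down in both comparisons against control, and Por (−0.58) and Ephx1 (−0.59) fell in tamoxifen+primidone against control. Members of these lists that passed in tamoxifen+primidone against control included Hand2, a stromal transcription factor (0.7), Gap43, a growth cone protein (1.53), Ptger4, a prostaglandin receptor (−0.65), and Ano1, a chloride channel (0.89).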

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

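The batch term, the counts without liver genes and the library weights were chosen after seeing the data; all other alternatives were planned, and all of them ran. Over 28 settings, the 162 named results gave 4488 values, of which 3795 kept direction and side of the threshold, 447 lost and 220 gained significance, and 26 changed sign. None of the 71 named results that passed changed sign. This was likely in advance, since library ranges did not overlap for 233 of 233, 2 of 2 and 811 of 812 called genes in the 3 comparisons. Arntl in tamoxifen against control kept its call in 28 of 28 settings (adjusted p from 5.5e-39 to 0.0071), Hgfac in tamoxifen+primidone against tamoxifen in 24 (1.1e-18 to 0.095) and Trpv6 in tamoxifen+primidone against control in 18 (0.00068 to 0.12). With 3 libraries per group, 58.3% to 65.3% of simulated 2-fold changes were recovered, which limits what counts of 0 can show. The cause of the changes below was not tested, except where fewer libraries or genes or another threshold entered by construction.

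Counts are given as higher and lower genes. DESeq2 gave 523 and 589 in tamoxifen against control, 211 and 367 in tamoxifen+primidone against tamoxifen, 894 and 988 in tamoxifen+primidone against control, 2299 among the 3 groups and 135 moved back, and limma-voom gave 50 higher in tamoxifen against control. In tamoxifen+primidone against tamoxifen, RLE factors gave 2 and 7 (2 moved back), upper-quartile factors 1 higher, no filter 3 and 18 (5 moved back), and removal of the gene-length trend 3 and 12 (4 moved back). A filter of 1 CPM or dispersions without the robust option gave 1 lower there and 0 moved back. Fitting only the groups compared gave 226 and 320 in tamoxifen against control and 0 moved back. An adjusted p with a 2-fold limit gave 45 and 75 in tamoxifen against control, 111 and 93 in tamoxifen+primidone against control, 236 among the 3 groups, 0 moved back and 0 TRP genes. An unadjusted p with a 2-fold limit gave 358 and 341, 201 and 183, and 290 lower in the 3 comparisons, 914 among the groups and 145 moved back. A surrogate variable gave 220 and 318, 13 and 57, and 728 and 842, with 1346 among the groups, 13 moved back and 2 TRP genes. FPKM with limma gave 659 higher in tamoxifen+primidone against control with a pseudocount of 1, and with 0.1 gave 646 and 316 there, 1 lower in tamoxifen+primidone against tamoxifen and 0 moved back. Without a filter on FPKM it was 51 and 92 in tamoxifen against control, 0 lower in tamoxifen+primidone against tamoxifen, 236 lower in tamoxifen+primidone against control, 323 among the groups and 0 moved back.

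With replicate number as a block, tamoxifen+primidone against tamoxifen gave 5 and 48 genes and 12 moved back, and with the gene-length trend also removed 5 and 43, 12 moved back and 133 higher in tamoxifen against control. With the GC trend removed in the blocked fit it was 7 and 45, with 13 moved back. Correlations of same-numbered libraries ran from −0.134 to 0.177, and not every library correlated best with its own number, so the numbers were not taken to pair libraries. Gene lists past camera fell to 0, 1 and 0 in the 3 comparisons with an estimated correlation and 0, 2 and 0 with fry.

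A term setting tamoxifen replicates 1 and 2 apart from the other libraries by their liver transcripts, so that the tamoxifen group rests on replicate 3, gave 17 and 5 genes in tamoxifen against control, 0 lower and 10 lists in tamoxifen+primidone against tamoxifen, 243 among the groups and 0 moved back. Library weights gave 295 and 399 in tamoxifen against control, 539 higher in tamoxifen+primidone against control and 1070 among the groups. Leaving out 1 library gave 9 to 168 higher and 13 to 271 lower in tamoxifen against control, 0 to 62 and 0 to 23 in tamoxifen+primidone against tamoxifen, and 41 to 316 and 81 to 484 in tamoxifen+primidone against control. It gave 59 to 664 among the groups, 0 to 49 moved back, 0 to 1 TRP genes and 5 to 9 lists in each comparison of tamoxifen+primidone.

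Changes of sign were found in log2 fold changes of TRP genes that did not pass. For Pkd2, tamoxifen+primidone against control, they were 0.025 with upper-quartile factors, 0.00107 with a 1 CPM filter, 0.000565 with the block, 0.0635 with the surrogate variable, 0.0298 without the length trend, 0.0378 with the block as well, 0.0642, 0.0728 and 0.0642 with the FPKM settings and 0.00367 with library weights, and −0.0508 to 0.0453 with 1 library left out. Trpm3, tamoxifen+primidone against tamoxifen, gave −0.0822 with the surrogate variable and −0.291 to 0.589 with 1 library left out. Trpv6, tamoxifen against control, gave −0.00654 with GC trend and block, −0.292 with the batch term and −0.126 to 0.213 with 1 library left out. Leaving out 1 library also gave −0.202 to 0.0131 for Pkd2, tamoxifen against control, −0.0163 to 0.197 for Pkd2, tamoxifen+primidone against tamoxifen, −0.0368 to 0.117 for Trpv4, tamoxifen against control, −0.153 to 0.376 for Trpv4, tamoxifen+primidone against tamoxifen, and −0.0988 to 0.43 for Trpv4, tamoxifen+primidone against control.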

Other observations

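The marker lists of clock, liver, natural killer cell and other organ genes, and the tests on clock genes, on Klra receptors and on primidone as the cause of the liver transcripts, were chosen after the values were seen. Of 11 clock genes that are known to peak with Dbp, 8 fell in tamoxifen against control, with Per3 at −2.28 ± 0.2 (edgeR adjusted p = 0.0015) and Tef at −1.81 ± 0.2 (adjusted p = 0.0072), and 9 fell in tamoxifen+primidone against control. Of 5 that peak with Arntl, 2 rose in tamoxifen against control and 3 in tamoxifen+primidone against control, in both cases including Nfil3 (1.58 ± 0.26 and 1.05 ± 0.26). In tamoxifen+primidone against tamoxifen 0 of these 16 genes passed with edgeR. Arntl stood at 8.57, 8.41 and 10.6 CPM in control, 35.4, 42.7 and 35.9 in tamoxifen and 31.1, 37.3 and 32.3 in tamoxifen+primidone libraries. The 11 genes that peak with Dbp were less uniform. Their median log2 level over the control mean was −1.17 in tamoxifen+primidone 1, against −1.99 and −1.9 in replicates 2 and 3.

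Of 40 liver genes, 39 were tested, and 5 rose in tamoxifen against control, 0 in tamoxifen+primidone against tamoxifen and 22 in tamoxifen+primidone against control, with medians of 0.94, 0.84 and 1.85. Alb, albumin, stood at 32.3, 30.8 and 30.7 CPM in control, 62.1, 56.1 and 101 in tamoxifen and 94.6, 95.8 and 93.5 in tamoxifen+primidone libraries. Of 5 natural killer receptor genes picked for being read mainly in tamoxifen-dosed libraries, Klra1 and Klra8 rose in tamoxifen against control, and Klra1, Klra8, Klra10 and Klrc3 rose in tamoxifen+primidone against control. Tamoxifen 3 stood apart, with a summed level of the 5 genes of 1.431 CPM against 12.25 and 8.633 in the other tamoxifen libraries and up to 0.8299 in control libraries. Of 10 natural killer cell genes outside that cluster, 1 rose in tamoxifen against control and 4 in tamoxifen+primidone against control, in the latter including Eomes, a transcription factor (1.81 ± 0.32). Of the other organ lists, 1 of 8 tested brain genes, Stmn2, fell in tamoxifen against control (−1.41 ± 0.28), and in no comparison did any of the 2 kidney, 1 pancreas, 6 heart and 3 intestine genes tested pass.

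For the liver transcripts, primidone as the whole cause is argued against by tamoxifen against control, where the lower quartile of the list was 0.7. Tamoxifen 3 carries much of this. The median log2 level of the list over the control mean was 0.59, 0.29 and 1.64 in tamoxifen 1, 2 and 3. It was −0.02 to 0.1 in control libraries and 1.64, 1.9 and 1.82 in tamoxifen+primidone libraries. A piece of liver carried along at dissection, in an amount of its own for each animal, would scatter within groups. The median SD within groups stood at percentile 82.4 of 10000 random lists (75.9 in control, 99.6 in tamoxifen and 0 in tamoxifen+primidone libraries), which leaves this open. Reads of a liver library sequenced alongside may also account for the liver transcripts. Of the 21 liver genes not looked at beforehand, 95.2% were positive in tamoxifen+primidone against control. Liver tissue would give the same value, so this share does not tell the sources apart. The genes of the liver list were also read in each control library, some with very few reads, and Uox, Alb and Rbp4 had the highest levels. The groups thus differ in the amount of these transcripts. Ttr is in the list of endometrial glands too.

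For the clock genes, a single library as the source is argued against, since the gap between the median log2 fold changes of the Arntl and Dbp groups was 2.74 in tamoxifen against control and at least 2.49 with any of the 6 libraries left out. A difference in the time of day at harvest between control and tamoxifen-dosed mice is a candidate explanation. The gap of 2.04 in tamoxifen+primidone against control is what it predicts, but a lasting effect of neonatal tamoxifen would give it as well. The labels give no time of harvest, so these cannot be told apart.

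For the Klra receptors, a shift of counted reads between family members as the whole cause would leave their sum unchanged. The sum of 11 Klra genes had a log2 ratio of 1.78 in tamoxifen+primidone to control (5.12 to 17.6 CPM). Reads left uncounted for matching several copies would change the sum, so this argues only against a shift among counted reads. More natural killer cells may account for part of the rise, since 10 other genes of these cells had a median log2 ratio of 1.1 (range 0.16 to 1.81) and the 7 other Klra genes together stood at 4.75 and 7.43 CPM. The 5 receptors had ratios of 3.59 to 5.97, but they were picked because they were read mainly in tamoxifen-dosed libraries and rest on 5 to 16 counts over the control libraries, so this gap excludes nothing. Another genetic background of the control mice at this cluster may account for the 3.9% left in control libraries, 0.509 against 13.1 CPM, but a strain is not given in the sources used here. More such cells, background and an effect of treatment on these genes cannot be told apart.

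Splits of the libraries that gave as many calls were counted for each result, and each count includes the real split. For 6 libraries there are 10 splits, too few for a share under 0.05. In tamoxifen against control 1 split gave as many as 233 genes (highest other 1) and 3 gave as many as 11 lists (highest other 12). In tamoxifen+primidone against tamoxifen 3 gave as many as 2 genes and 6 as many as 5 lists (highest other 14). The highest other split there, with 40 genes, set tamoxifen+primidone 1 and 3 and tamoxifen 3 against the rest, and another gave 30, which points to a structure of these libraries besides the groups. In tamoxifen+primidone against control 1 gave as many as 812 genes (highest other 0) and 4 as many as 8 lists (highest other 12). Of 100 splits of the 9 libraries, only the real one gave as many as 583 genes differing among 3 groups (highest other 308). The next 3 splits, with 308, 151 and 75 genes, each kept the 3 control libraries together. A random split of all 9 libraries thus seldom gave such a count, which rests largely on control libraries against the rest. It does not exclude chance for a difference between tamoxifen and tamoxifen+primidone libraries. For the TRP gene, 1 split gave as many as 1 (highest other 0). This count came from the pairwise comparisons, whose totals were not kept for each split. By the F test, all except 3 of the other splits called at most 3 genes, so the count says little about TRP genes. For the gene moved back, 5 splits gave as many as 1 (highest other 93), and chance is not excluded; the split with 93 kept the 3 control libraries together.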
